A study of Homo sapiens with 4 samples.

How the data were processed

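RNA was sequenced from 4 cultures of HT29, an established human colon adenocarcinoma cell line. Per the labels' protocols, cells grown to 90% confluency in medium with 5% serum were transfected with a miR-23b precursor, with an antimir against miR-23b, or with the respective control of either, at 50 nM (written "50nm" in the labels) with Lipofectamine 2000. The medium was replaced after 24 h and RNA was taken with Trizol after 48 h, per the labels' protocols. A precursor is a synthetic RNA that raises the level of a microRNA, and an antimir is an oligonucleotide that binds and blocks one. Each of the 4 groups held 1 library, so no group had a replicate.

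Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 1.8.3, aligned to hg19 with TopHat2 2.0.11, and quantified and compared with Cufflinks 2.2.0 and Cuffdiff. The order and settings of these steps, and the annotation used, were not given in the sources used here. The authors deposited 2 tables, each comparing 1 treated library with 1 other library, as FPKM per isoform, a read density scaled to transcript length and library size. Per the file headers, each table also held the authors' p-value and q-value and a call of significance for each isoform. The authors' p-value and q-value compare 2 libraries, not 2 conditions, because no replicates entered them. The library named with a final N in each table was taken as the control, as it was the only other library there. The labels' protocols name an identical library tag for 2 index sequences, which left the tag of each library unclear but did not enter any grouping. FPKM values carry no read counts, so the depth of each library is unknown and no counting interval or detection floor is given.

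Each table held 212874 entries for 53617 genes, of which 168036 were transcripts and 44838 carried a gene identifier in place of a transcript. These gene-identifier entries look like whole-locus, unspliced forms, but no source says how they were made. They were used only for the 11192 genes with no transcript entry, of which 96.7% of those matched in the reference annotation were single-exon. Entries with a failed status (1321 in the precursor table and 1528 in the antimir table) were left out, which removed 116 and 131 genes with no other isoform. A gene's FPKM was the sum over its remaining transcripts. Differences were taken between log2(FPKM + 1) of the treated library and of its control, for genes with a mean FPKM of at least 1 over the 2 libraries, and centred on the median of those genes. A fold change on this scale understates the change of low genes. The median removed was 0.022 in the precursor comparison, -0.038 in the antimir comparison and 0.35 in the comparison of the control libraries, where the tables had been normalised separately. Genes past 1.5-fold were counted without any test, since 1 library per group gives no replicate error.

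The design, the alternatives, the rule for named genes and 21 gene lists were fixed before the data were examined. The lists were reported miR-23 targets, the miR-23 loci with microRNA pathway genes, colon stem cell markers, Wnt targets, Notch, TGF-beta and SMAD genes, drug response, apoptosis, proliferation, enterocyte, goblet and enteroendocrine markers, epithelial adhesion and mesenchymal transition, interferon-induced genes, stress response, p53 targets, hypoxia and glycolysis, sterol synthesis, markers of other cell types, ribosomal proteins and mitochondrially encoded transcripts. Each list is described by its median difference and by the percentile of that median among 10000 random lists of equal size matched in 20 bins of mean expression. These percentiles describe the libraries at hand and are not p-values. Mitochondrial list members were required to lie on the mitochondrial genome, a choice made after seeing the data because a nuclear copy shared a symbol. The named genes were the 8 highest and 8 lowest per comparison (without small RNAs, read-through loci and genes without a name), up to 3 members of each list with the largest differences (not all of which are given here), a fixed set of reported miR-23 targets, stem cell markers and miR-23 loci, and 5 genes with opposite differences in the 2 comparisons. A few genes named by the rule or in the lists are not reported here by name, though list medians include them. Genes outside this rule are said to be chosen after their values were seen.

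Seed sites were 7-mers complementary to bases 2 to 8 of miR-23b-3p, and 8-mers with an added A, in the longest 3' UTR of each gene. The UTRs came from GENCODE 29, which is built on another assembly than the authors' tables, so it was matched by identifier only and none of its coordinates were used. Of the gene identifiers, 46998 (87.7%) matched. The difference between the medians of genes with and without a site was set against 10000 random lists matched in 10 bins of expression and 10 bins of UTR length. All 7-mers present in at least 200 genes were also ranked by the ratio of their difference to its SE, after adjustment for expression, UTR length and UTR GC content, with differences clipped at 0.5. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

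The procedure was tested on simulated data in which 200 genes were changed by known folds and noise of 0.15 log2 units was added to each library. For the precursor comparison, with 16895 genes, it recovered 38.8% of genes changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 3-fold, and 0.222% of unchanged genes passed the threshold. For the antimir comparison, with 14124 genes, the shares were 20.8%, 95.9% and 100%, with 0.380% of unchanged genes past the threshold. A 7-mer shifted by -0.05 ranked first by this ratio in both simulations. That shift was larger than the miR-23b-3p site differences found in the data, so it does not tell how a shift of their size would rank. The simulated noise was equal at all expression levels, unlike the data. Per isoform, the standard error implied by the authors' p-values was 0.146 log2 units at 10 to 50 FPKM and 0.419 at 1 to 2 FPKM (precursor). In the antimir table it was 0.492 and 1.60. The simulated shares of unchanged genes past the threshold therefore do not give the share of false genes in the data.

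The settings also tried were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, a fold threshold of 2, no centring, the most abundant isoform in place of the sum, all isoforms whatever their status, q-value limits of 0.01 and 0.1, other site and UTR definitions, and Pearson's correlation in place of Spearman's. Protein-coding genes alone, tested isoforms alone, no gene listed at 0, and inclusion of the gene-identifier entries were chosen after seeing the data. In these alternatives the random lists numbered 2000 for gene lists and 1000 for sites. The level of mature miR-23b was not analysed here.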

Results

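The series asked which mRNAs respond to miR-23b in colon cancer cells, in the setting of stem cell self-renewal and drug resistance. Expression was measured by RNA sequencing in 4 libraries of HT29 colon cancer cells: precursor, precursor control, antimir and antimir control, with 1 library each. At an FPKM of at least 1, the precursor library held 16809 genes (11337 protein-coding) and its control 16718 (11328). The antimir library held 14120 genes (11053 protein-coding) and its control 13908 (11054). The 10 most abundant genes took 40.0% of all FPKM in the precursor library, 37.1% in its control, 46.2% in the antimir library and 46.4% in its control. No difference in any comparison has a replicate check, and all gene differences are centred log2(FPKM + 1) differences between the treated library and its control.

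The first comparison asks which genes differ when miR-23b is raised. In the precursor library, genes of DNA replication and mitosis were lower and interferon-induced genes were lower, while Wnt targets, goblet cell markers, and hypoxia and glycolysis genes were higher. Colon stem cell markers were higher in the sum over isoforms, but within the random range when only the most abundant isoform was used. These were small differences spread over many genes. CENPE, the kinetochore motor of mitosis, was at 19.2 FPKM in the precursor library and 29 in its control (-0.59). AXIN2, a feedback inhibitor and target of Wnt signalling, was at 22.6 against 15.6 (0.49). NDRG1, a gene induced by low oxygen, was at 261 against 181 (0.50).

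Neither microRNA precursor gene of the miR-23 family gave a value. MIR23B and MIR23A were listed at 0 in all 4 libraries. In hg19, the locus given for MIR23B spans chromosome 9, 97488983 to 97849441, and is shared with C9orf3, the gene that hosts it. C9orf3 was at 14.7 FPKM in the precursor library and 14.8 in its control. MIR27B, a neighbour in the miR-23b cluster, was at 41.9 against 35.8 FPKM, and MIR24-1 was at 115 in the precursor library and listed at 0 in its control. Over the 15 measured genes of the miR-23 loci and the microRNA pathway, the median difference was -0.12, at percentile 0.69 of the random lists. With the most abundant isoform in place of the sum, that median turned to 0.027 (percentile 68.95). TNRC6A, which encodes a partner of the Argonaute proteins, was at 25.4 against 34.6 FPKM (-0.46, and -0.077 with its most abundant isoform only), with 1 isoform called higher and 0 lower by the authors. TNRC6B was at 1.75 against 0.825 (0.57), a value from which isoforms holding 69.9% of its FPKM had been left out as failed, and 0.15 with those kept.

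Genes reported elsewhere as miR-23 targets showed no common direction in the precursor library. Of 30 measured, 13 lay above 0 and 17 below, the median was -0.0050 (percentile 44.5), and none was past 1.5-fold either way. The members with the largest differences were APAF1, the core of the apoptosome, at 12.8 against 14.5 FPKM (-0.19, but -0.075 with tested isoforms alone, and with 2 isoforms called higher and 0 lower by the authors), STX12 at 20.3 against 22.9 (-0.19) and SMAD3 at 49.2 against 42.4 (0.19). MET, the hepatocyte growth factor receptor, was at 150 FPKM in both libraries (-0.023), with 2 isoforms called lower and 0 higher by the authors. Of the measured targets, 12 had an isoform called higher by the authors and 10 had one called lower. SMAD4 was at 3.87 against 4.04, TGFBR2 at 31.0 against 32.5, SMAD5 at 33.4 against 31.2 and FZD7 at 3.67 against 3.28. PLAU (0.117 and 0.0506) and ZEB1 (0.711 and 0.315) stayed below a mean FPKM of 1.

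Of the 36 proliferation genes, 31 lay below 0 and 5 above, with a median of -0.14 at percentile 0 of the random lists. CDC45, part of the replicative helicase, was at 49.3 FPKM in the precursor library against 62.8 (-0.36), and CDK1, the mitotic kinase, at 173 against 213 (-0.32). The CENPE locus lies on chromosome 4, 104026963 to 104119566, in hg19. Interferon-induced genes had a median of -0.17 over 22 measured members, with 17 below 0, also at percentile 0. IFIT1, IFIT2, IFIT3 and IFIT5 gave no value in the precursor table, where all their isoforms had failed, though they were measured in the antimir table. IFI44L was at 7.75 against 13.5 (-0.75) and XAF1 at 2.46 against 4.45 (-0.68), while ISG20, an exonuclease, was at 17.8 against 11 (0.62).

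Wnt targets were higher as a group, with 17 of 23 above 0 and a median of 0.14 (percentile 99.9). The AXIN2 locus lies on chromosome 17, 63524685 to 63557765, in hg19. PROX1 was at 1.82 FPKM in the precursor library against 0.989 (0.48), and TCF7 at 30.1 against 22.8 (0.36). Stem cell markers had a median of 0.14 over 19 genes (percentile 99.5), with 13 above 0 and none past 1.5-fold. With the most abundant isoform only, their median was 0.058, inside the random range (percentile 86.25). ALCAM was at 5.89 against 4.18 (0.39, but -0.0069 with its most abundant isoform only), LGR5, a receptor marking intestinal stem cells, at 3.81 against 3.10 (0.21), PROM1 at 76.5 against 67.7 (0.15), CD44 at 734 against 657 (0.14) and ALDH1A1 at 719 against 673 (0.073). The authors called 2 isoforms of CD44 higher and 4 lower, and 1 of ALDH1A1 lower. LRIG1 was at 12.2 against 10.8 (0.14), and BMI1 at 123 against 120 (0.0044).

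Goblet cell markers were also higher as a group. They had a median of 0.19 over 12 genes (percentile 99.9), and of 0.36 over 11 genes with the most abundant isoform only, led by TFF3, a secreted trefoil peptide, at 12.6 against 7.89 FPKM (0.60), and the mucin MUC5AC at 8.31 against 6.07 (0.37). Enterocyte markers had a median of 0.10 over 15 genes (percentile 97.2), within the central 95% of random lists, with FABP1 at 18.7 against 12.9 (0.48). ISL1 was the 1 enteroendocrine marker past the filter, at 7.75 against 7.54.

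Of 24 hypoxia and glycolysis genes, 21 were above 0, with a median of 0.17 (percentile 100), or 0.099 with the most abundant isoform only (percentile 98.2). ALDOC, a glycolytic aldolase, was at 38.6 against 24.6 FPKM (0.61) and CA9, a carbonic anhydrase induced by low oxygen, at 68.9 against 52.3 (0.37). Stress response genes had a median of 0.089 over 24 genes (percentile 98.6), but 0.056 with the most abundant isoform only, inside the random range (percentile 86.95). TRIB3 was at 37.1 against 30.7 (0.24), while EDEM1, which acts in the disposal of misfolded proteins, was at 10.1 against 12.8 (-0.33, and -0.0070 with its most abundant isoform only). TGF-beta and SMAD genes had a median of 0.076 over 22 genes (percentile 95.7). PMEPA1 was at 32.4 against 25.3 (0.32). Drug response genes had a median of -0.028 over 32 genes (percentile 16.6) and diverged. ATP7A, a copper exporter, was at 9.53 against 5.98 (0.57), the drug efflux pump ABCC5 at 4.69 against 7.10 (-0.53) and the folate carrier SLC19A1 at 16.8 against 12.2 (0.41). Apoptosis genes had a median of 0.012 over 29 genes (percentile 59.6), with the BH3-only gene BBC3 at 9.32 against 6.41 (0.46).

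The make-up of the RNA differed beside these groups. All 12 mitochondrially encoded transcripts were above 0, with a median of 0.33 (percentile 100), and took 2.08% of FPKM in the precursor library against 1.61%. MT-CO1 was at 6538 FPKM against 5001 (0.36). Ribosomal protein genes had a median of 0.081 over 36 genes (percentile 98.0) and took 4.37% against 4.03%, with the percentile inside the central 95% at 94.85 with the most abundant isoform only and at 96 at a mean FPKM of at least 5. Markers of other cell types stayed low, with 4 of the list past the filter and a median of 0.19 (percentile 91.7). CD68 was at 5.59 against 4.18 and CD14 at 2.76 against 1.74.

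Among single genes, most of the largest precursor differences belonged to pseudogenes or genes listed at 0 in 1 library. TMSB10P2 was at 9.39 FPKM and listed at 0 in the control, TMSB4XP3 at 6.73 and at 0, POLR2KP1 at 5.24 and at 0, ALG13-AS1 at 4.25 and at 0, BAGE4 at 3.49 and at 0, and RPL39P40 at 2.41 and at 0. SPTLC1P2 was at 25.5 against 6.57 (1.78). MRPS36P3, HIST1H2APS3 and C1orf195 were listed at 0 in the precursor library and at 4.55, 4.30 and 2.81 in the control. TAB3-AS2 was at 0.747 against 6.02 (-2.03) and HEATR7B1 at 0.238 against 3.36 (-1.84). DIO1, a thyroid hormone deiodinase, was at 0.379 against 273 FPKM (-7.66), with none of its isoforms tested in the authors' deposited table. EFR3A was at 1.12 against 8.37 (-2.17) and DHX37 at 5.42 against 0.152 (2.46), but isoforms left out as failed held 93.0% and 71.4% of their FPKM, and with those kept the differences were 0.13 and 0.12. The last of the 8 lowest, RN18S1, is named after a ribosomal RNA, annotated as a processed pseudogene and given without values here. It was lower, and among the 8 highest and 8 lowest it alone had an isoform called in the authors' table.

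Of 16982 genes in the precursor comparison, 571 were at least 1.5-fold higher and 564 lower (6.68%). Among 11346 protein-coding genes the numbers were 57 and 71 (1.13%). The authors' deposited table called 5453 entries higher and 7049 lower in the precursor library, of 86200 tested, with gene-identifier entries counted. Among transcripts alone, 5402 were called higher and 5207 lower, so the excess of lower calls came from gene-identifier entries. Of the entries called, 2583 (20.7%) were listed at 0 in 1 library. Counted as genes with an isoform called, these calls were 9 higher and 8 lower for Wnt targets, 6 and 5 for goblet markers, 9 and 6 for stem cell markers, 16 and 10 for hypoxia genes and 9 and 5 for stress response genes. They were 10 and 16 for proliferation genes, 4 and 11 for interferon genes, 6 and 7 for the miR-23 loci and pathway, 1 and 0 for mitochondrially encoded transcripts, and 9 and 21 for ribosomal protein genes, opposite to the direction of that list's median. Of the gene lists, 10 lay outside the central 95% of random lists, and 7 with the most abundant isoform only, where 1 would be expected of lists of unrelated genes. The fixed lists share members and their genes may vary together. That expectation therefore does not tell how many lists would differ between 2 untreated cultures.

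The second comparison asks which genes differ when miR-23b is blocked. In the antimir library, interferon-induced genes stood far above the control, with 25 of 27 at least 1.5-fold higher and none lower. Ribosomal protein genes and mitochondrially encoded transcripts were lower. Proliferation genes were higher, and Wnt targets and TGF-beta and SMAD genes lower, in the sum over isoforms, but these 3 groups lay within the random range when only the most abundant isoform was used. IFI44L was at 81.1 FPKM in the antimir library and 9.64 in its control (2.99), and IFI6, an interferon-induced membrane protein, was at 814 against 163 (2.35).

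The interferon list had a median of 1.26, at percentile 100, where random lists spanned -0.093 to 0.082. All 27 members were above 0. OAS2, a sensor of double-stranded RNA, was at 77.5 against 15.5 FPKM (2.28). IFITM1, an antiviral membrane protein outside the list, was at 119 against 14.9 (2.95). Chosen after their values were seen, MX1 was at 61.7 against 14.9 (2.02), IFI27 at 2738 against 915 (1.62) and ISG15 at 432 against 159. In hg19, IFI44L lies on chromosome 1 at 79085607 to 79108484, and IFI6 on the same chromosome at 27992572 to 27998729. In the authors' deposited table, 14 of the listed genes had an isoform called higher in the antimir library and 0 had one called lower. For IFI44L 3 isoforms were called higher there, for IFI6 2 and for OAS2 1.

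**Figure D1:**
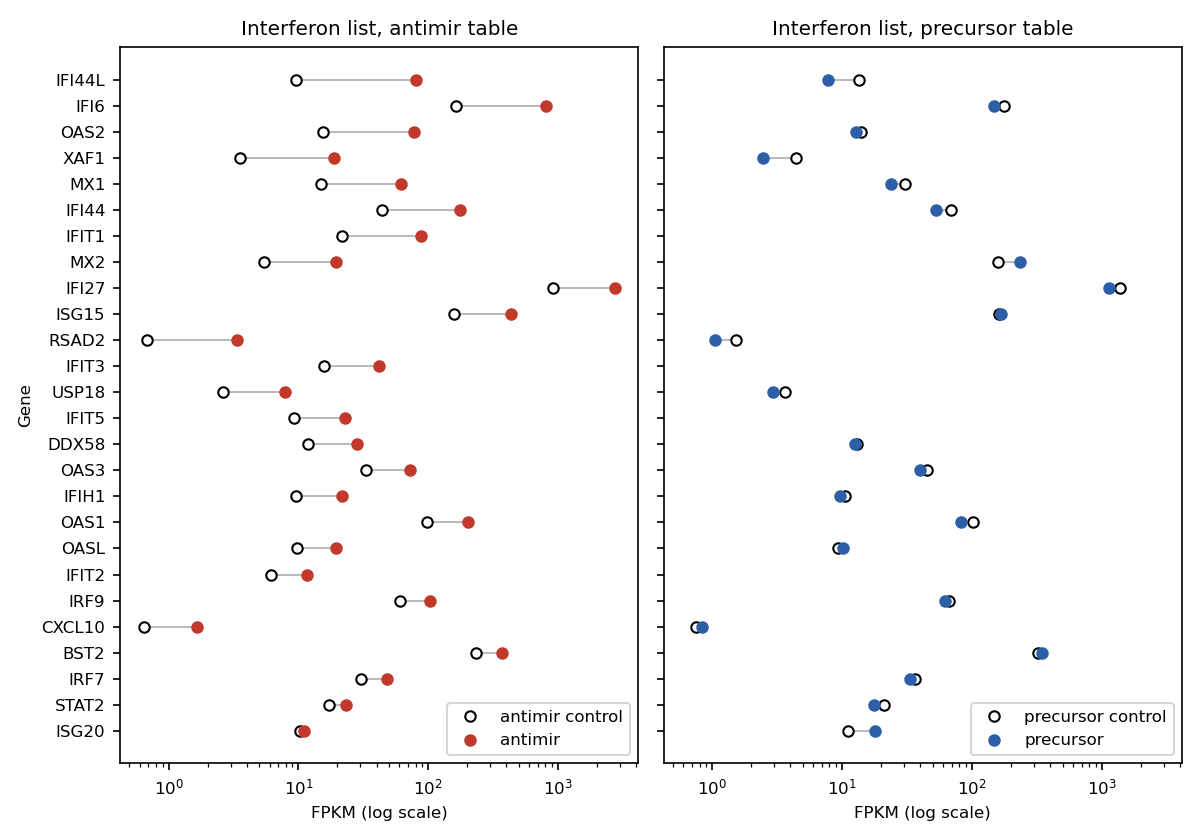
FPKM (log scale) of interferon list genes in the antimir table (left; filled red, antimir; open, its control) and the precursor table (right; filled blue, precursor; open, its control), 1 library per point and a line joining each pair. IFI44L runs from 9.64 to 81.1 FPKM on the left and from 13.5 down to 7.75 on the right. IFIT1, IFIT2, IFIT3 and IFIT5 have no point on the right, as all their isoforms had failed in the precursor table.

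Proliferation genes had a median of 0.11 over 36 genes in the antimir library (percentile 99.9), with 27 above 0. With the most abundant isoform only it was 0.061 (percentile 92.2). CENPE was at 25.6 against 13.3 FPKM (0.93), the spindle checkpoint kinase BUB1B at 55.2 against 40.1 (0.49, but -0.011 with its most abundant isoform only) and TTK at 25.6 against 18.9 (0.46). Ribosomal protein genes had a median of -0.24, with 35 of 36 below 0 (percentile 0), and took 4.55% of FPKM against 5.20% in the control. RPL3 was at 854 against 1204 (-0.46) and RPLP0 at 2194 against 3075 (-0.45). All 12 mitochondrially encoded transcripts were below 0, with a median of -0.32 (percentile 0), and took 2.2% against 2.61%. MT-ND5 was at 821 against 1225 (-0.54) and MT-CO3 at 3338 against 4666 (-0.45).

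Reported miR-23 targets again had no common direction, with 11 of 28 above 0 and a median of -0.058 (percentile 11.2). SMAD5 was at 3.38 against 7.13 FPKM (-0.85), with isoforms holding 77.9% of its FPKM left out as failed, and -0.38 with those kept. FAS, a death receptor, was at 4.04 against 2.55 (0.54, but 0.087 with tested isoforms alone). MET was at 92.1 against 92.4, SMAD3 at 25 against 28.1, SMAD4 at 4.36 against 3.94, TGFBR2 at 30.5 against 32.9 and FZD7 at 3.09 against 3.59. PLAU was at 0.104 and listed at 0, and ZEB1 at 0.620 against 0.489. Genes of the miR-23 loci and the microRNA pathway had a median of -0.16 over 13 genes (percentile 0.83), which lay inside the random range at a mean FPKM of at least 5 (-0.096, percentile 5.9), with the most abundant isoform only (-0.042, percentile 27.35) and with tested isoforms alone (-0.033, percentile 30.4). EIF2C2, which encodes Argonaute 2, was at 51.1 against 78.3 (-0.57), and C9orf3 at 14.1 against 13.0 (0.15).

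Stem cell markers were mixed, with 10 of 19 above 0 and a median of 0.022 (percentile 66.95) that became -0.16 at a mean FPKM of at least 5. HOPX was at 2.84 against 0.545 FPKM (1.35), CD44 at 473 against 588 (-0.28), LGR5 at 3.32 against 4.24 (-0.24), PROM1 at 46.0 against 54.0 (-0.19), LRIG1 at 7.59 against 8.94 (-0.17), BMI1 at 87.0 against 99.96 (-0.16) and ALDH1A1 at 551 against 557 (0.022). Wnt targets had a median of -0.11, with 18 of 23 below 0 (percentile 1.19). It lay inside the random range at a mean FPKM of at least 5 (percentile 3.35), with the most abundant isoform only (-0.052, percentile 17.75) and with tested isoforms alone (percentile 4.5). SP5 was at 6.27 against 9.21 (-0.45) and FOSL1 at 3.33 against 4.95 (-0.42, but 0.091 with its most abundant isoform only), while TCF7L2 was at 48.1 against 38.9 (0.34). TGF-beta and SMAD genes had a median of -0.12, with 18 of 22 below 0 (percentile 1.11), and of -0.059 with the most abundant isoform only, inside the random range (percentile 12.4). TGFB2 was at 3.72 against 5.91 (-0.51, but 0.049 with its most abundant isoform only).

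Stress response genes had a median of -0.091 over 24 genes (percentile 2.78), just inside the random range, and lay outside it with a pseudocount of 0.1 (percentile 0.75) and with the most abundant isoform only (-0.12, percentile 0.5). CHAC1, which degrades glutathione, was at 3.97 against 10.1 FPKM (-1.12), the transcription factor ATF3 at 5.98 against 11.6 (-0.81) and the cystine transporter SLC7A11 at 12.2 against 19.8 (-0.62). Drug response genes had a median of -0.029 over 32 genes (percentile 25.4). TYMP, thymidine phosphorylase, was at 2.72 against 0.792 (1.09) and the copper importer SLC31A1 at 4.81 against 7.56 (-0.52). Apoptosis genes had a median of 0.064 over 29 genes (percentile 92.4), with BIRC3 at 3.39 against 1.72 (0.73). Hypoxia and glycolysis genes had a median of -0.022 over 25 genes (percentile 39.3), with ANKRD37 at 4.45 against 3.24 (0.40).

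Goblet markers had a median of 0.0061 over 13 genes (percentile 50.8). The mucin MUC1 was at 1.47 against 3.86 FPKM (-0.94, and -2.00 with its most abundant isoform only) and MUC13 at 46.1 against 37.0 (0.35). Enterocyte markers had a median of -0.032 over 14 genes (percentile 28.6), with CDHR5 at 10.3 against 14.4 (-0.41). ISL1 was at 6.09 against 5.46. Of the markers of other cell types, 3 passed the filter, with a median of 0.050 (percentile 54.8), and ITGAM was at 0.555 against 1.65.

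Other large antimir differences again included pseudogenes and partly failed genes. HLA-Z was at 160 FPKM and listed at 0 in the control, HCG9 at 16.1 and at 0, and PPIAP20 at 4.59 and at 0. Listed at 0 in the antimir library were SPTLC1P2 (8.54 in the control), MICF (6.54), HIST1H2APS3 (5.59), TMSL6 (5.43) and BAGE4 (4.07). FBXL16 was at 9.07 against 0.542 (2.74). SOX10, a neural crest transcription factor, was at 0.0192 against 4.96 (-2.51), and NT5DC4 at 0.0484 against 4.39 (-2.33). HBS1L was at 8.15 against 0.000804 (3.23), COQ2 at 7.46 against 0.410 (2.62) and TOP2B at 0.0831 against 7.34 (-2.91). With failed isoforms kept, these 3 differences were 0.059, -0.036 and 0.017. Low genes depend on the pseudocount, and at 0.1 and 5 the HOPX difference was 2.23 and 0.53, that of TYMP 1.70 and 0.44, and that of SOX10 -5.37 and -0.96.

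Of 14190 genes in the antimir comparison, 720 were at least 1.5-fold higher and 411 lower (7.97%). Among 11060 protein-coding genes the numbers were 195 and 95 (2.62%). The authors' deposited table called 157 entries higher and 108 lower in the antimir library, of 67879 tested. Among transcripts alone, 151 were called higher and 106 lower. Of the entries called, 149 (56.2%) were listed at 0 in 1 library. Among the other lists outside the random range, 1 proliferation gene had an isoform called higher, 1 Wnt target and 2 TGF-beta and SMAD genes had one called lower, and no gene of the ribosomal protein, mitochondrially encoded or miR-23 lists had one called. Of the gene lists, 7 lay outside the central 95% of random lists, and 4 to 8 under the other settings, where 1 would be expected of lists of unrelated genes. As for the precursor lists, that expectation does not hold for differences between untreated cultures.

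**Figure D2:**
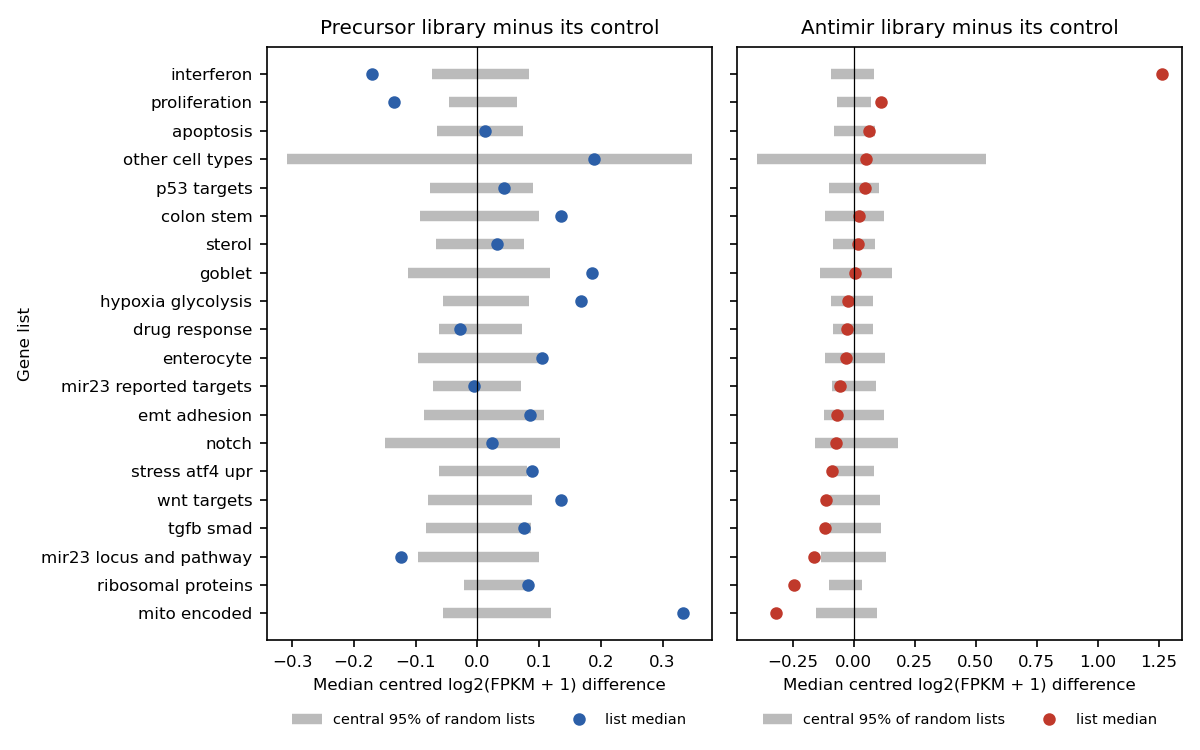
Median centred log2(FPKM + 1) difference of each gene list (points) in the precursor (left, blue) and antimir (right, red) comparison, over the central 95% range of random lists matched on expression (grey bars). The interferon list lies at -0.17 on the left and 1.26 on the right.

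Whether genes with a miR-23b-3p seed site differed from other genes was asked across all expressed genes. In the precursor comparison, 2488 of 11297 genes had a 7-mer site, and their median lay 0.035 log2 units below that of other genes (difference -0.035, random lists -0.012 to 0.0034, percentile 0). Of site genes, 56.4% were below 0, against 46.5% of the others. The 1191 genes with the longer 8-mer site had a median of -0.034 and the 1297 with 7-mer sites only had -0.012. After adjustment for expression, UTR length and GC content, the site had a difference of -0.023 (SE 0.0044) and ranked 3 of 14747 7-mers from the lowest by the ratio of difference to SE. CTGGAGA ranked 1 by that ratio and ATGTGAA, the 8-mer site without its first base, ranked 2. ATGTGAA, in 2591 genes, was not itself scored as a site, so genes with it alone count as having no site throughout. By the difference alone, the site ranked 99, CTGGAGA 72 and ATGTGAA 85. In the antimir comparison, site genes differed from others by -5.4e-05 (2448 of 11023 genes), above the range of random lists (-0.025 to -0.0074, percentile 100). After adjustment the site ranked 7955 of 14695 there by the same ratio.

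Sites of 3 related microRNAs served as comparison. In the precursor library, genes with a site for miR-23b-5p, from the opposite arm, differed by 0.024 (percentile 100), those for miR-27b-3p by -0.012 (percentile 3.46) and those for miR-24-3p by 0.017 (percentile 100). In the antimir library the differences were -0.033 (percentile 0.04), -0.0068 (percentile 91.4) and -0.038 (percentile 0). After the same adjustment the precursor differences were 0.014, -0.0026 and 0.0017, against -0.023 for miR-23b-3p, and the antimir differences were 0.0013, 0.0043 and -0.0045.

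**Figure D3:**
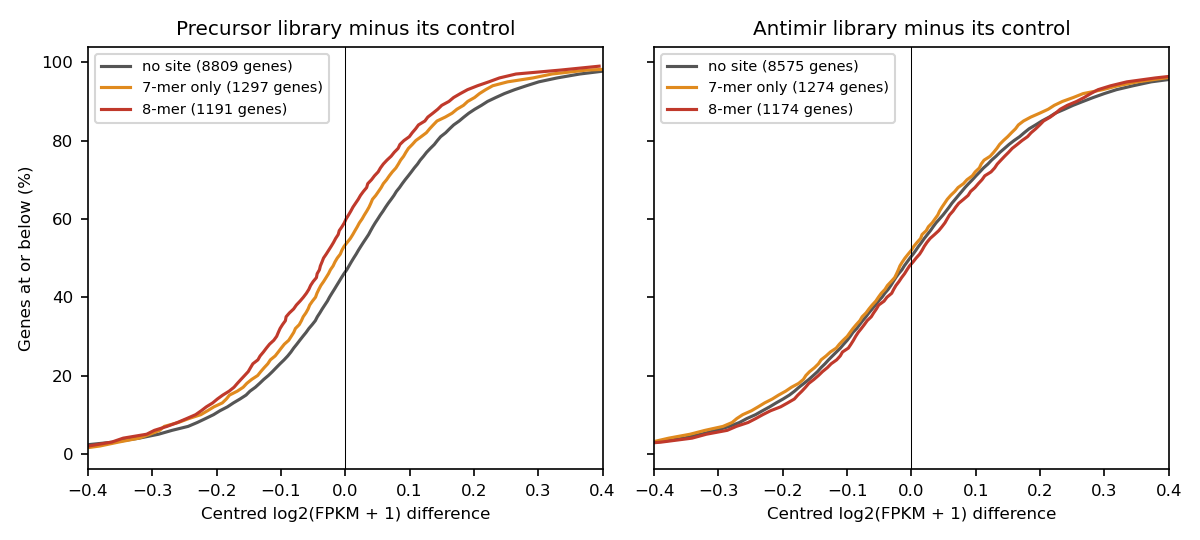
Cumulative share of genes (%) against the centred log2(FPKM + 1) difference in the precursor (left) and antimir (right) comparison, for genes with no miR-23b-3p site (grey), 7-mer sites only (orange) and an 8-mer site (red). On the left the median is 0.013 with no site, -0.012 with 7-mer sites only and -0.034 with an 8-mer site.

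Across the 13757 genes measured in both comparisons, the precursor and antimir differences had a Spearman correlation of -0.156, and -0.192 among 10970 protein-coding genes. These are correlations across genes, which are not independent replicates, and Pearson's r was 0.087. Past 1.5-fold, 60 genes were higher with the precursor and lower with the antimir where independent lists would share 5.93, and 101 were lower and then higher against 13.4. The same direction held 92 genes higher in both against 9.90, and 64 lower in both against 8.06, so the excess was not particular to opposite directions. Of genes past 1.5-fold, 970 of 1135 (precursor) and 791 of 1131 (antimir) were small RNAs, read-through loci or genes without a name. Among protein-coding genes, 3 and 10 lay in opposite directions against 0.466 and 1.04, and 5 and 4 in the same direction against 0.897 and 0.543. Of the 20 lists with a value in both comparisons, 11 had medians of opposite sign. The interferon, proliferation, Wnt target, ribosomal protein and mitochondrially encoded lists lay outside the central 95% in both comparisons, in opposite directions. Of these 5, the interferon and mitochondrially encoded lists did so under each of the 4 other settings run for lists, while the proliferation, Wnt target and ribosomal protein lists fell inside in 1 of the comparisons with the most abundant isoform only. At a mean FPKM of at least 5, the ribosomal protein list also fell inside in the precursor comparison and the Wnt target list in the antimir comparison. With tested isoforms alone, the antimir Wnt target list fell inside as well. The miR-23 loci and microRNA pathway genes were outside in the same direction in the main setting, but neither median was outside with the most abundant isoform only, where the signs differed. C10orf116 was at 5.44 against 1.59 FPKM with the precursor (1.29) and 1.41 against 4.28 with the antimir (-1.09). C15orf63 was at 1.85 against 6.27 (-1.37) and 3.65 against 0.604 (1.57). TAB3-AS2, lower with the precursor, was at 3.38 against 0.171 with the antimir (1.94), and SPTLC1P2 and BAGE4, higher with the precursor, were listed at 0 with the antimir.

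The control libraries were compared as a measure of the difference between libraries given neither treatment. Of 16141 genes, 3439 were at least 1.5-fold higher in the precursor control and 712 in the antimir control (25.7%), and of 11223 protein-coding genes 869 and 149 (9.07%). These tables were normalised separately and differ in which genes are listed at 0, with 335 genes at 10 FPKM or more in both precursor-table libraries and at 0 in both antimir-table libraries, and 19 the other way. Interferon list genes measured in both tables had a median FPKM of 28.6 in the precursor library, 33.6 in its control, 67.2 in the antimir library and 16.4 in its control. These medians are neither centred nor paired by gene, so they do not place the antimir control below the precursor table. Compared gene by gene and centred on all genes, the antimir control stood at 0.18 relative to the mean of the precursor-table libraries.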

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

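The comparison of gene-identifier entries was chosen only after the data were seen, and no cause was tested. These entries, which carry a gene identifier in place of a transcript and whose making no source describes, lay outside the comparisons for genes that also had transcript entries, and in the antimir library they stood above the control. Their median log2 ratio of antimir to control was 0.0435 over 9351 entries, with 41.6% below 0. The median log2(FPKM + 1) difference of genes at a mean FPKM of at least 1, before centring, was -0.038. The entries were instead taken at a mean FPKM of at least 0.1, so these medians differ in scale and filter. In the precursor library the median was -0.316 over 9863 entries, with 85.6% below 0, where that of genes, on their own scale and filter, was 0.022. The medians depend on the level of the gene's transcripts. Where their mean FPKM was under 0.1, the antimir median turned to -0.0217 over 746 entries (53.1% below 0) and the precursor median was -0.0832 over 762 (61.9% below 0). Where it was 1 or more, the medians were 0.0491 over 7647 and -0.336 over 8051. Of all gene-identifier entries, also those of genes with no transcript entry, the authors called 1842 lower and 51 higher in the precursor library. In the antimir library they called 2 lower and 6 higher.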

How the results depend on the processing

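Protein-coding genes alone, tested isoforms alone, no gene listed at 0 and inclusion of gene-identifier entries were chosen only after the results were seen. No paired analysis was possible because each group held 1 library, and no library could be left out. Depth is unknown, so counting error cannot be bounded for low genes. Counts and correlations were taken to stay if within 1.5 times the reported value, list medians and site differences if within 0.5 of the width of their random 95% range, and genes if within 0.58 log2 units, so a list that stayed can still leave or enter the random range. A turn was counted for genes past 1.5-fold, for lists and sites outside the random range and for the correlation, so smaller values can change sign uncounted, as those of ALCAM, BUB1B, FOSL1 and TGFB2 did with the most abundant isoform only. Counts, site differences, list summaries and correlations stayed in 52 recomputed values, moved in 31 and changed sign in 7. List medians stayed in 151, moved in 3 and turned in 1, and named genes stayed in 728, moved in 74 and turned in 3. Of the moved gene values, 34 came from a pseudocount of 0.1 and 36 from a pseudocount of 5, which by construction widen or narrow the differences of low genes. The cause was not tested for any of these unless stated. Fewer genes pass a stricter filter or threshold by construction. With a pseudocount of 5, genes past 1.5-fold were 369 lower with the precursor, and 463 higher and 212 lower with the antimir. At a mean FPKM of at least 5 they were 277 higher and 348 lower (precursor), 408 and 214 (antimir) and 2344 between controls. At 2-fold, 333 were lower with the precursor, and 449 higher and 224 lower with the antimir. Without a filter 655 were lower with the antimir, and 643 with the most abundant isoform only, where 4 antimir lists in place of 7 lay outside the random range. Protein-coding genes alone gave 57 and 71 (precursor), 195 and 95 (antimir) and 1018 between controls. Tested isoforms alone gave 351 higher with the precursor and 2149 between controls. Without genes listed at 0, 276 were higher with the precursor and 424 with the antimir. At a q-value under 0.01 the authors' deposited table held 3272 entries higher and 3983 lower (precursor) and 97 and 54 (antimir). These counts include gene-identifier entries and were not split from transcripts.

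The precursor site difference was -0.047 with 8-mers only, -0.047 with at least 2 sites and -0.026 with the UTR of the most abundant or shortest isoform. The antimir site difference, near 0, was 0.0095 with 8-mers, 0.0052 with at least 2 sites, 0.00099 with a pseudocount of 0.1, 0.00081 at a mean FPKM of at least 5, 0.013 with the most abundant isoform, 0.0012 with tested isoforms alone and -0.0092 with the other UTR. The correlation of the comparisons turned to 0.087 with Pearson's method. With the most abundant isoform the precursor median of the miR-23 loci and pathway turned to 0.027, goblet markers moved to 0.36 and hypoxia genes to 0.099. With the most abundant isoform only, the precursor stem cell, stress response, ribosomal protein and miR-23 lists and the antimir proliferation, Wnt, TGF-beta and miR-23 lists fell inside the random range, and 7 precursor lists in place of 10 lay outside. Stem cell markers in the antimir library moved to -0.16 at a mean FPKM of at least 5. With failed isoforms kept, EFR3A turned to 0.13, COQ2 to -0.036 and TOP2B to 0.017 because those isoforms carry most of their FPKM.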

Other observations

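The tests of low control values, of other cell types, of interferon genes with no site and of 8-mer against 7-mer sites were chosen only after the results were seen. Several further fixed lists were not part of the account so far. In the precursor library, sterol synthesis genes had a median of 0.031 over 23 genes (percentile 77.6), with INSIG1, which restrains sterol synthesis, at 43.4 against 34.0 FPKM (0.32) and HSD17B7 at 13.0 against 16.4 (-0.34). Notch genes had a median of 0.024 over 10 genes (percentile 67.9), with DTX4 at 44.9 against 37.9 (0.22). Genes of epithelial adhesion and mesenchymal transition had a median of 0.085 over 13 genes (percentile 93.2), but lay outside the random range at a mean FPKM of at least 5 (0.11, percentile 98.45) and with the most abundant isoform only (0.14, percentile 99), with the junction protein JUP at 115 against 91.8 (0.30). p53 targets had a median of 0.044 over 23 genes (percentile 81.35), with CDKN1A, a cell cycle inhibitor, at 4.88 against 3.95.

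In the antimir library, sterol genes had a median of 0.017 over 23 genes (percentile 65.2), with LSS at 8.94 against 12.1 FPKM (-0.36), and Notch genes -0.074 over 10 genes (percentile 17.4), with the ligand JAG1 at 2.09 against 3.20 (-0.40). Epithelial adhesion genes had a median of -0.068 over 13 genes (percentile 12.9), 10 of them below 0, with CDH1, the epithelial cadherin, at 181 against 226 (-0.28). p53 targets had a median of 0.048 over 22 genes (percentile 83.2), with RRM2B, a ribonucleotide reductase subunit, at 21.0 against 10.4 (0.98, and 1.82 with its most abundant isoform only). The authors' deposited tables differ in how many isoforms they call. At an FPKM of 10 to 50 the standard error implied by their values was 0.146 in the precursor table and 0.492 in the antimir table, while the median absolute difference was 0.141 and 0.168.

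Interferon-induced genes were higher in the antimir library. Low values in its control are argued against, since relative to the mean of the precursor-table libraries, normalised separately and centred on all genes, the antimir library stood at 1.42 over 22 genes, 21 of them above 0, and its control at 0.18. Admixed cells are argued against only for the cell types that the 23 markers cover. Of these markers, 0 rose from under an FPKM of 1 in the control to 1 or more in the antimir library. CD68, CD14 and ITGAM were already above 1 in the control and could not count. CD68 was highest, at 5.14 against 4.16 FPKM, and ITGAM was lower, at 0.555 against 1.65. Cells that carry none of these markers would not be seen by this test, so for them it cannot decide. For loss of repression through the interferon genes' own miR-23b-3p sites, the test fixed beforehand could not tell. Of the genes, 5 (18.5%) had a 7-mer in the longest 3' UTR, where matched random genes gave 3.70 to 29.6% (median 14.8%). As the cause of the whole pattern, through that 7-mer, it is argued against by the 22 genes with none. Their median was 1.27 (random lists -0.0889 to 0.0828), with 20 past 1.5-fold. With 25 of all 27 past 1.5-fold, that outcome was known before this later test. Such loss stays open for the 5 with a 7-mer, and for any of the 22 with ATGTGAA, which was not searched for in them. A candidate explanation is a response of the cells to the transfected antimir, which cannot be separated from a difference between these particular cultures with 1 library each.

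The precursor and antimir differences had a negative rank correlation across genes, though Pearson's r was 0.087, and past 1.5-fold 92 and 64 genes lay in the same direction (higher or lower in both) against 60 and 101 in opposite ones. A trend with expression, transcript length and GC content alone is argued against, since the correlation was -0.159 before and -0.120 after removing such trends (95% bootstrap interval over genes -0.139 to -0.102, 13201 genes). The demand that this whole interval lie below -0.10 was added after the value was seen. Action on site genes alone is argued against by a correlation of -0.184 among 8507 genes with no site, against -0.214 among 2428 with one. Genes with ATGTGAA alone count here among those with no site. Opposite states of growth or RNA make-up in the cultures may contribute and were not tested.

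Genes with a miR-23b-3p site were lower in the precursor library. Base composition of the site is argued against by its percentile of 0.714 among 210 7-mers of equal composition, ranked by the ratio of difference to SE, and by the difference alone it ranked 2 among them. Expression level and UTR length are argued against by the difference of -0.0351, outside the matched range of -0.0120 to 0.00338. The median of 8-mer genes minus that of 7-mer-only genes was -0.0214 (95% bootstrap interval over genes -0.0329 to -0.00708), without matching on expression or UTR length. Action of the transfected precursor would give this order. Yet miR-23b-5p site genes showed it too, with medians of 0.014 (8-mer) and 0.035 (7-mer only). So, by smaller gaps, did those of miR-27b-3p (-0.0082 and -0.0030) and miR-24-3p (0.017 and 0.020). No interval was computed for the gaps of these other microRNAs. The order is thus not particular to miR-23b-3p and cannot decide, and action of the precursor remains a hypothesis. By the ratio of difference to SE the 7-mer CTGGAGA, no seed match of miR-23b, ranked lower than the site, for a cause that was not tested.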
